A study of Homo sapiens with 10 samples.

How the data were processed

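Macrophages from the pancreas of 5 donors were measured by 10x CITE-seq, with 1 messenger RNA library and 1 antibody library per donor. Replicates 1 to 4 were 3′ libraries with a panel of 140 antibodies and replicate 5 was a 5′ library with 137 antibodies and 10 hashtags, per the labels. The values used were counts: the deposited tables give raw UMI counts per gene and cell and raw counts per antibody and cell, whole numbers whose totals per cell equal those in the cell tables. The submitters' processing notes name Cell Ranger 6.0, the GRCh38 genome and Seurat, while the header of the deposited matrices names Cell Ranger 4, so the counting version is open. The authors selected the cells and genes, and their cell tables give each cell a cluster number at resolution 0.8, shared by all libraries and carrying no names. How these clusters were made, and whether the libraries were integrated first, is not stated. All 25115 genes of the tables were read. The T cell part of the series was not analysed. Hashtag counts were all 0 in the 3′ libraries, every cell of the 5′ library had the same hashtag, and no file said what it marks, so hashtags were not used.

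Each of the authors' clusters was named by code from marker lists. A marker counted when it reached 10 CPM and a log2 fold of 1 over the other clusters, with a pseudocount of 5 CPM, as the mean over libraries with at least 20 of the cluster's cells. A cluster took the name with the largest share of its list, and needed at least 3 markers. The general macrophage list named no subset. Names end in "-like" because they rest on RNA alone. Macrophages were all named macrophage, monocyte, cycling and unnamed clusters (36364 cells), and 3219 cDC2-like cells were left out. Shares are given per library with exact binomial 95% intervals, and doublets were kept. Doublet calls came from 1 simulated doublet per cell and 50 neighbours at an assumed 0.8% per 1000 cells, and marked 878, 1851, 302, 210 and 55 cells in replicates 1 to 5, used only in alternatives and in the tests of cycling and acinar RNA. Other cells' RNA was compared with barcodes of 10 to 100 UMIs and with barcodes of at least 1000 UMIs outside the deposited cells. A macrophage was above background for a cell type with at least 2 UMIs of its markers and more than the 99% quantile of a Poisson distribution at the library's mean share.

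Antibody signal was the centred log-ratio, log(count + 1) minus the cell's mean of it over all antibodies but isotype controls, in cells with at least 100 antibody counts. Within each library, macrophages were ranked by CD163 or CD11c and split into 3 parts of equal size. RNA counts were summed per library and class, with at least 50 cells per class. The sums of the highest and lowest parts were compared by edgeR's quasi-likelihood test with TMM, filterByExpr, the library as a block and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Cells are not replicates, and each p-value measures the spread between these libraries. The high and low sums of a library come from the same donor, which pairs them, and their deviations from the class means correlated at 0.774 or more for CD163 and 0.640 or more for CD11c. CPM values are means over libraries with SD, and folds per library use a prior count of 2. TMM factors lay between 0.929 and 1.09 for CD163 and between 0.889 and 1.11 for CD11c. For surface proteins, antibody counts were summed per library in each subset and in the other macrophages (at least 20 cells each, at least 3 libraries) and tested in the same way over the 129 antibodies shared by the panels. Gene lists were tested by camera with a preset correlation of 0.01, with an estimated correlation as an alternative, for lists with at least 3 members tested, leaving out the gene of the ranked antibody. The lists were also run through fry, which asks whether a list's genes move one way on balance against no change and does not compare them with other genes. The lists covered resident, lipid-associated and monocyte genes, MHC class II, dendritic cell, inflammatory, interferon, complement, scavenger receptor, lysosome, cholesterol, iron, stress, checkpoint, growth factor, hypoxia and proliferation genes, and markers of acinar, endocrine, T and NK, B and plasma, stromal, neutrophil and mast cells. For RNA against protein, Spearman's rho was taken across the macrophages of a library between CPM and antibody signal. One gene was matched to each antibody, and the pair was kept when it was measured in all 5 libraries and at least 1% of cells had its RNA. Of 125 matched antibodies, 122 had RNA, 100 were in all libraries and 72 were kept.

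Comparisons, lists and the rule for naming genes were fixed before the data were examined. The rule took genes past an adjusted p of 0.05 that moved the same way in every library at a mean log2 CPM of at least 5, and named the 10 largest rises and 10 largest falls. It left out mitochondrial and ribosomal protein genes, immunoglobulin and T cell receptor segments, unnamed loci, XIST, Y-linked genes and the gene of the ranked antibody. Per list it allowed up to 4 members with the smallest p, and per subset the 6 largest antibody rises and falls past the threshold. Some genes that the rule selects are not reported here. List members named for their direction among 5 or fewer calls, and pairs in the part on RNA against protein, were chosen after their values were seen. A contrast on CD206 was not run because no panel held that antibody, and a contrast between tissues or compartments because no file names them per cell. The labels give no donor phenotype, so no donors were compared.

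Depth, spread and the number of libraries together set what could be seen. Simulated counts had the depth of these sums and an assumed spread, the same for all genes and not measured from them. In these, edgeR found 44% of changes of log2 0.5 and 99% of log2 1.5 for CD163 (13919 genes, 4 false calls), and 41% and 98% for CD11c (13771 genes, 10 false calls). For antibodies, also at an assumed spread, it found 20 of 20 changes of log2 0.5 in each of the 4 named subsets, with 2, 0, 4 and 2 false calls for cycling, LYVE1/FOLR2, lipid-associated and monocyte-like cells. Changes in genes or antibodies that vary more than assumed would be found less often. The camera code found a planted list of 15 genes in both contrasts. The mean Spearman estimate over 200 runs lay within 0.00205 of each simulated value, and single runs can err more.

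Alternatives were RLE factors, DESeq2, no count filter, a mean count of at least 50, no library block, classes above and below the median, antibody counts per 10000 in place of the log-ratio, isotype correction, thinning to 2000 UMIs, a mitochondrial limit of 5%, leaving out 3292 cells with other cells' RNA above background, limma on log-ratio means, library size only, and leaving out each library. The authors' clusters were also replaced by Leiden clusters at resolutions 0.5 and 1.5, from 2000 variable genes, 30 principal components and 15 neighbours. Added after seeing the data were cDC2-like cells kept, cycling cell-like cells and cluster 7 left out, with or without cluster 10, classes taken within each cluster, called doublets removed, unnamed clusters tested by number and the whole 3′ panel tested in its 4 libraries. In up to 100 other splits of the sums, with the same block, the number of calls was taken again. Random seeds were 1. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.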

Results

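Pancreatic macrophages of 5 human donors were profiled by CITE-seq, an assay that counts messenger RNA and DNA-tagged surface antibodies in the same single cells. The series concerns the immune cells of the pancreas in obesity, but the labels used here carry no donor phenotype, so all donors formed 1 group and donors were not compared with one another. Each donor gave 1 RNA library and 1 antibody library, and the donor is the replicate throughout (n = 5). Replicates 1 to 4 were 3′ libraries stained with 140 antibodies, and replicate 5 was a 5′ library stained with a related panel, with 129 antibodies and 6 isotype controls among the reagents shared by all panels. The deposited tables held 10478, 15210, 6147, 5128 and 2620 cells in replicates 1 to 5, 39583 cells in all. RNA depth was 54384105, 81598936, 65718886, 42794911 and 27742353 UMIs per library, with medians of 4438, 4608, 9627, 7794 and 6738 UMIs per cell. Antibody depth was 9844992, 14376588, 6029917, 4075023 and 6562676 counts, with medians of 835, 814, 845, 692 and 2315 per cell. Median mitochondrial shares were 7.07%, 6.85%, 5.84%, 7.48% and 2.13%.

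The first question was which macrophage populations the pancreas held. Cells of 12 deposited clusters were named from marker lists, and the genes that define a cluster serve here only as its definition. Lipid-associated macrophage-like cells, named from genes such as GPNMB and CD9 and known from lipid-laden tissue, made up 22.8% ± 7.55 of cells (SD, n = 5). They join cluster 2 (14.0% ± 7.37), which also carried LPL and FABP4, and cluster 4 (8.83% ± 0.874), named on SPP1, CD9 and GPNMB alone. Cluster 1, which took no name, had TREM2 at 876 and SPP1 at 8403 CPM. These were 613 and 8631 CPM in cluster 2 and 1017 and 14808 CPM in cluster 4. LYVE1/FOLR2 macrophage-like cells, named for the hyaluronan receptor and the folate receptor of tissue-resident macrophages, made up 20.8% ± 4.20. This class joins cluster 0 (19.0% ± 4.33) and cluster 10 (1.72% ± 1.40), whose leading genes include FOLR2 and LYVE1 but mostly DNA replication genes such as MCM6, MCM4 and E2F1. Monocyte-like cells, led by VCAN, FCN1 and S100A8, made up 16.8% ± 5.09, and cDC2-like cells, led by CLEC10A and CD1C, 8.42% ± 2.03. In this cDC2-like cluster CLEC10A and CD1C were highest of all clusters, but at only 85.8 and 22.0 CPM. Its C1QA (3792 CPM) and CD163 (1211 CPM) were above those of clusters 1, 2 and 4, which were kept as macrophages. The name therefore does not set these cells apart from macrophages. Interferon macrophage-like cells were rare, at 0.117% ± 0.0753 or 37 cells, and were too few to test.

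Cycling cell-like macrophages made up 6.12% ± 4.15 and showed the widest relative range among the larger classes. They formed 11.3% of cells in replicate 1 (95% exact binomial interval 10.7 to 11.9%, 1183 of 10478 cells) and 0.995% in replicate 4 (0.741 to 1.31%, 51 of 5128 cells), and the lowest share without replicate 4 was 3.5%, in replicate 3. Clusters 1 and 7 carried too few markers of any list and stayed unnamed. Cluster 1, led by C3, OLFML3, ADGRG1 and CX3CR1, made up 20.2% ± 10.6, and cluster 7, led by the DNA replication genes GINS2, HELLS and MCM6, 4.76% ± 2.89. The intervals cover counting error only, and the shares also reflect the isolation of macrophages and the authors' choice of cells. Shares moved with the clustering. With own clusters at resolutions 0.5 and 1.5 the lipid-associated share was 10.5% and 14.0% and the cDC2-like share 20.9% and 5.26%, and the monocyte-like share was 6.97% at 0.5. The cycling cell-like name then also took a cluster led by GINS2 and HELLS (1973 and 1410 cells), genes that lead cluster 7. Cycling cells with at least 100 antibody counts numbered 1908 and 1916 in replicate 1, against 1181 with the authors' clusters. In replicate 4 they numbered 11 at both resolutions, against 50. The cluster named cDC2-like at 0.5 had EREG, THBS1, ANPEP, TFPI and CCR2 among its 10 leading genes, as monocyte-like cluster 3 of the authors had, so its share is no count of cDC2-like cells alone. Among cells at 5% mitochondrial RNA or less the LYVE1/FOLR2 share was 12.5%.

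**Figure D1:**
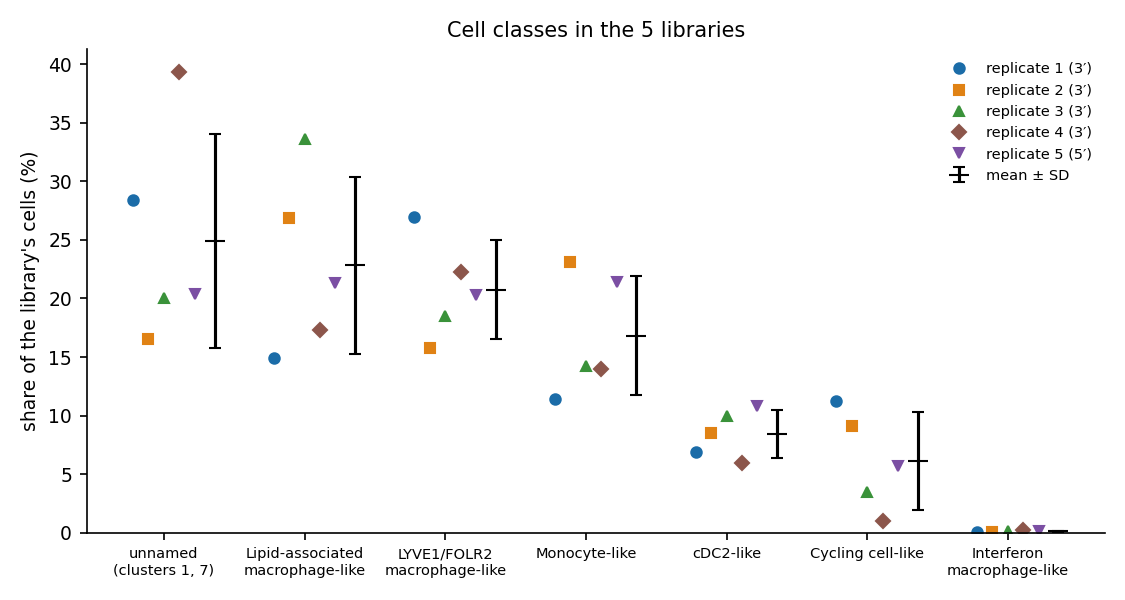
Share of each library's cells (y axis, percent) in each cell class (x axis); symbols are the 5 libraries and the bar is the mean with SD. The unnamed clusters range from 16.5% to 39.3% and the cycling cell-like class from 0.995% to 11.3%.

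The second question was how RNA differed between macrophages with much and little CD163 on their surface. CD163 is the haemoglobin scavenger receptor, often used as a marker of tissue-resident macrophages. Of 36364 macrophages, 36283 with at least 100 antibody counts were ranked by CD163 signal within each library and split into 3 parts of equal size, of which the highest and the lowest were compared. SELENOP, a secreted selenium carrier, rose in CD163-high macrophages with a log2 fold change of 3.92 (SE 0.19, edgeR adjusted p = 6.33e-07), from 72.3 ± 52.0 to 1045 ± 495 CPM (SD, n = 5). LYVE1 rose by 3.69 (SE 0.22, adjusted p = 1.88e-06), from 43.1 ± 23.4 to 552 ± 231 CPM. FOLR2 rose by 3.29 (SE 0.13, adjusted p = 2.47e-07), from 19.8 ± 5.38 to 192 ± 43.2 CPM, and MRC1, the mannose receptor CD206, by 2.76 (SE 0.27, adjusted p = 5.5e-05), from 199 ± 142 to 1134 ± 370 CPM. The other large rises were in LILRB5 (3.60, SE 0.18), the coagulation subunit F13A1 (2.98, SE 0.15), the iron exporter SLC40A1 (2.78, SE 0.13), RND3 (2.54, SE 0.11), RGL1 (2.54, SE 0.17) and the scavenger receptor COLEC12 (2.51, SE 0.22), each higher in 5 of 5 libraries.

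CD163-low macrophages carried more podoplanin, complement C3 and osteopontin RNA. PDPN, which encodes podoplanin, fell by 2.27 on the log2 scale (SE 0.08, adjusted p = 1.52e-07), from 69.3 ± 31.2 CPM in CD163-low to 14.1 ± 5.88 CPM in CD163-high cells. C3 fell by 1.98 (SE 0.13, adjusted p = 6.3e-06), from 589 ± 246 to 141 ± 32.9 CPM, and SPP1, the gene of osteopontin, by 1.57 (SE 0.18, adjusted p = 0.000148), from 11253 ± 3861 to 3961 ± 1923 CPM. OLFML3 (−2.21, SE 0.11), PADI2 (−1.95, SE 0.14), RGS16 (−1.87, SE 0.15), the tight junction gene CLDN1 (−1.82, SE 0.09), HAMP, which encodes the iron hormone hepcidin (−1.58, SE 0.13), PLD4 (−1.55, SE 0.10) and SCIN (−1.53, SE 0.09) also fell, each in 5 of 5 libraries. The gene CD163 itself, which checks the antibody and is no finding, was higher by 1.29 (SE 0.13, adjusted p = 8.1e-05).

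In all, 3056 genes were higher and 2859 lower of 13895 tested by edgeR's quasi-likelihood test with the library as a block (n = 5 pairs). Of these, 5028 moved the same way in every library, 374 were higher and 328 lower by 2-fold or more, and the median log2 fold change of all genes was 0.02. In the 4 libraries of 3′ end alone, 3098 genes were higher and 3452 lower, and the 5′ end has 1 library and no test of its own. Without the block, 132 were higher and 65 lower. Without replicate 1 the lower genes numbered 1877. Among macrophages at 5% mitochondrial RNA or less, 1606 were higher and 1846 lower, and 1057 and 1103 when the parts were taken within each cluster, an alternative added after seeing the data.

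The classes are ranges of 1 signal and not cell types. Of 36283 macrophages, 8294 (22.9%) lay within 0.1 of a threshold between parts, and the median antibody count was 21.8 ± 4.87 in the high and 5.4 ± 1.67 in the low class. Median RNA depth was 6131 ± 2223 UMIs in CD163-high and 8515 ± 3716 in CD163-low cells. Median total antibody counts were 1062 ± 662 in CD163-high and 1158 ± 755 in CD163-low cells. LYVE1/FOLR2 macrophage-like cells made up 46.9% ± 11.3 of the high and 5.77% ± 3.80 of the low class, and cluster 1 made up 4.60% ± 1.75 and 35.3% ± 17.4. Medians over cells gave 6450 ± 802 CPM of resident macrophage genes in high against 940 ± 358 in low cells, 7384 ± 1281 against 18920 ± 3744 CPM of lipid-associated genes, and 4361 ± 1364 against 2386 ± 882 CPM of monocyte genes. For dendritic cell genes they were 236 ± 33.6 and 340 ± 60.6 CPM, and for MHC class II genes 17489 ± 7217 and 20770 ± 9620 CPM. Each value sums the CPM of a list's genes in a cell, so abundant members weigh most. In the lipid-associated list these include SPP1, whose fall is given above, and the list as a whole did not pass camera.

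**Figure D2:**
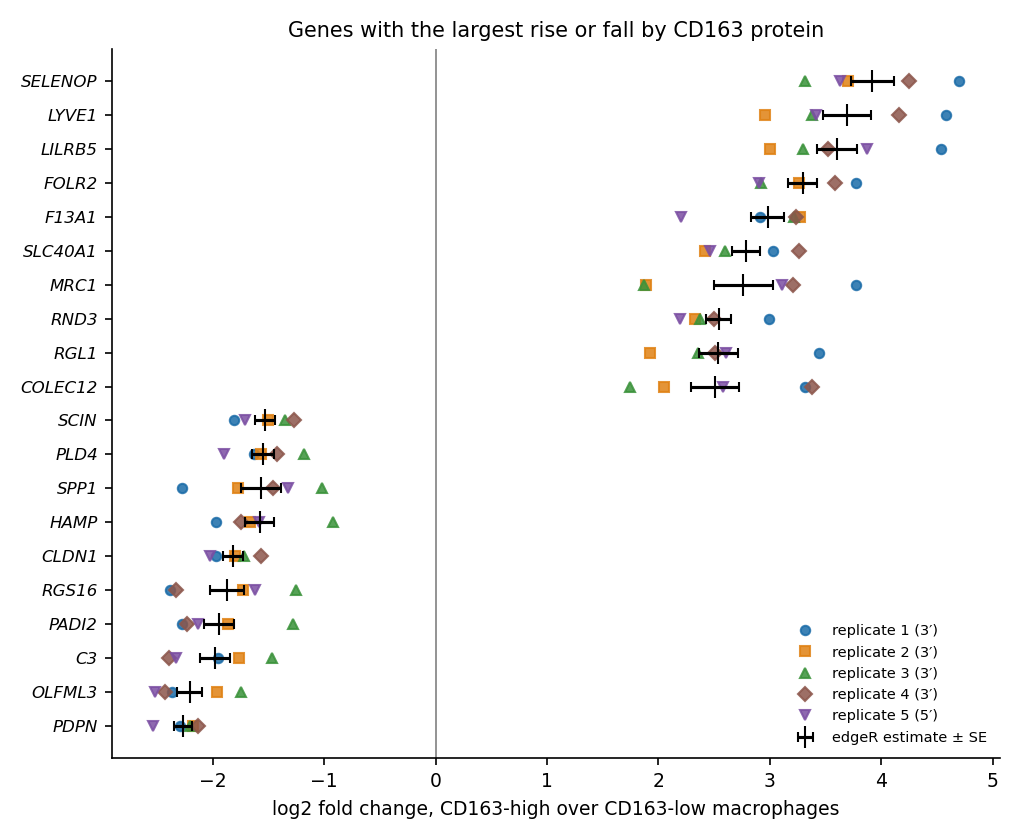
Log2 fold change of CD163-high over CD163-low macrophages (x axis) for the 10 largest rises and 10 largest falls (y axis). Symbols are the 5 libraries and the black bar is the edgeR estimate with SE, from 3.92 for SELENOP to −2.27 for PDPN.

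Gene lists were then set against all other genes with camera, with values given as log2 fold change ± SE (n = 5). Of 15 resident macrophage genes tested, 14 rose and 1 did not pass the test, 14 also when adjusted over the list alone. They included the lectin CD209 (3.57 ± 0.14), and the list was higher with adjusted p = 5.75e-46, or adjusted p = 0.0549 with an estimated correlation. Of 13 complement genes, 11 rose, 1 fell and 1 did not pass, with 12 and 1 adjusted over the list alone. The complement receptor CR1 (2.77 ± 0.10), the C1 inhibitor SERPING1 (2.30 ± 0.11) and C2 (1.29 ± 0.12) rose and C3 fell (camera adjusted p = 1.22e-08, and adjusted p = 0.0666 with an estimated correlation). Of 13 scavenger receptor genes, 9 rose, 1 fell and 3 did not pass, the same counts as adjusted over the list alone, with STAB1 at 1.89 ± 0.10 and CD163L1 at 2.31 ± 0.17 (adjusted p = 4.04e-07, and adjusted p = 0.151 with an estimated correlation). Of 9 iron and haem genes, 5 rose and 4 did not pass, 5 also adjusted over the list alone, among them SLC40A1, the biliverdin reductase BLVRB (1.19 ± 0.15) and the ferritinophagy receptor NCOA4 (0.54 ± 0.10). The iron list had adjusted p = 0.000164, or adjusted p = 0.0977 with an estimated correlation.

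Of 12 monocyte genes, 10 rose and 2 did not pass, 10 also adjusted over the list alone, with THBS1 at 1.85 ± 0.13 and CD300E at 1.10 ± 0.12 (camera adjusted p = 0.000133, and adjusted p = 0.436 with an estimated correlation). Of 15 inflammatory genes, 9 rose, 1 fell and 5 did not pass, the same adjusted over the list alone. The chemokines CXCL2 (0.89 ± 0.11) and CXCL3 (1.18 ± 0.19) and the prostaglandin synthase PTGS2 (0.82 ± 0.11) rose, with list adjusted p = 0.00605, or adjusted p = 0.151 with an estimated correlation. Of 16 cholesterol and lipid handling genes, 8 rose, 2 fell and 6 did not pass, with 10 and 2 adjusted over the list alone. The cholesterol exporter ABCA1 rose (1.23 ± 0.11, with list adjusted p = 0.0213, and adjusted p = 0.302 with an estimated correlation). Of 16 dissociation stress genes, 8 rose and 8 did not pass, 8 also adjusted over the list alone, with EGR1 at 0.86 ± 0.10 and HSPA6 at 0.55 ± 0.08. That list, a sign of tissue handling, moved with the groups above (adjusted p = 0.0126, and adjusted p = 0.620 with an estimated correlation).

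Of 12 proliferation genes, 11 fell and 1 did not pass, and 12 fell when adjusted over the list alone (camera adjusted p = 0.000164, adjusted p = 0.555 with an estimated correlation and adjusted p = 0.0575 with fry, which tests against no change and not against other genes). The values were −1.19 ± 0.24 for TYMS, the thymidylate synthase, and −0.93 ± 0.21 for the cell cycle kinase CDK1. Without cycling cell-like cells and cluster 7, an alternative added after seeing the data, TYMS stood at 1.53 and CDK1 at 0.89, the opposite direction, with cluster 10 kept. With cluster 10 left out too, also added, TYMS was −0.042 and CDK1 −0.38, and neither passed. Of 12 T and NK cell genes, 3 fell, IL7R (−0.95 ± 0.11), CCL5 (−1.19 ± 0.17) and GNLY (−0.79 ± 0.17), and 9 did not pass, 3 also adjusted over the list alone (adjusted p = 0.0148, and adjusted p = 0.436 with an estimated correlation). GNLY did not pass without replicate 2, where it was −0.57.

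The other lists did not pass camera in the CD163 contrast. Of 16 lipid-associated genes, 4 rose, 5 fell and 7 did not pass, with 5 and 6 adjusted over the list alone. The lipid receptor TREM2 fell (−1.03 ± 0.10) and the fatty acid binding protein FABP4 rose (1.82 ± 0.40), at adjusted p = 0.170 for the list. Of 13 MHC class II genes, 1 rose and 2 fell, the same adjusted over the list alone, with the protease CTSS at 0.59 ± 0.11 and HLA-DQA1 at −0.47 ± 0.10 (list adjusted p = 0.279). Counts of HLA genes are uncertain because near-identical copies can share reads, as are those of HSPA1A and HSPA1B. Of 11 dendritic cell genes, 2 rose and 3 fell, the same adjusted over the list alone, with CLEC10A at 1.94 ± 0.18 and PKIB at −1.31 ± 0.12 (list adjusted p = 0.975). Of 14 interferon genes, 1 rose and 3 fell, the same adjusted over the list alone, with ISG15 at −0.51 ± 0.11 (list adjusted p = 0.982). The interferon list had a median and mean log2 fold change of 0.14, while camera placed it lower than other genes.

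Of 19 lysosome genes, 4 rose and 2 fell (LIPA 0.52 ± 0.12, LAMP1 0.50 ± 0.12, list adjusted p = 0.538). Of 14 checkpoint and costimulation genes, 6 rose and 2 fell (LILRB2 1.3 ± 0.10, HAVCR2 −0.48 ± 0.08, list adjusted p = 0.279, and adjusted p = 0.0245 with fry). Of 15 growth factor and matrix genes, 6 rose and 3 fell (IGF1 2.23 ± 0.29, PDGFC 1.72 ± 0.15, FN1 −1.06 ± 0.11, list adjusted p = 0.524). Of 13 hypoxia and glycolysis genes, 3 rose and 5 fell (BNIP3 0.82 ± 0.09, HK2 −1.18 ± 0.15, list adjusted p = 0.538). These 4 lists had the same counts adjusted over the list alone. Among markers of other cells, 0 of 14 acinar genes passed edgeR or DESeq2 in either direction, also adjusted over the list alone, and 3 by edgeR and 1 by DESeq2 were higher at an unadjusted p under 0.05 (list adjusted p = 0.335). Of 5 B and plasma cell genes, DERL3 fell (−1.3 ± 0.16, list adjusted p = 0.362). Of 4 stromal and endothelial genes, PECAM1 rose (0.34 ± 0.07) and PLVAP fell (−0.79 ± 0.28, list adjusted p = 0.968), and PLVAP did not pass without replicate 1 (−0.71), 4 (−0.85) or 5 (−0.53). Of 5 neutrophil genes, FFAR2 rose (0.76 ± 0.15) and G0S2 (−1.04 ± 0.23) and CXCR2 (−0.89 ± 0.21) fell (list adjusted p = 0.810). Of 3 mast cell genes, HPGDS fell (−0.91 ± 0.18, list adjusted p = 0.335). Counts adjusted over the list alone were the same for these 4 marker lists, and endocrine genes had too few tested members. Median and mean differed in sign for the neutrophil list (0.17 and −0.16), and both were negative for the stromal list (−0.05 and −0.14) while camera placed it higher.

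The third question was how RNA differed with surface CD11c, the integrin subunit encoded by ITGAX and used to mark macrophages of lipid-laden tissue. The apolipoprotein APOE rose with a log2 fold change of 2.38 (SE 0.27, edgeR adjusted p = 0.000456), from 1837 ± 1002 CPM in CD11c-low to 8508 ± 3092 CPM in CD11c-high cells (SD, n = 5). APOC1 rose by 2.32 (SE 0.18, adjusted p = 0.000116), from 572 ± 314 to 2925 ± 1652 CPM, osteopontin (SPP1) by 2.30 (SE 0.26, adjusted p = 0.000467), from 2372 ± 926 to 11954 ± 4288 CPM, and GPNMB, a lysosomal membrane glycoprotein, by 1.96 (SE 0.16, adjusted p = 0.000179), from 145 ± 97.4 to 549 ± 347 CPM. CHI3L1, a chitinase-like secreted protein, had the largest rise (4.22, SE 0.30, adjusted p = 0.000109), from 4.53 ± 7.77 to 82.1 ± 126 CPM. Replicate 3 carried most of that RNA, and without it the means were 1.10 and 29.3 CPM, with a log2 fold change of 4.38. APOC2 (2.35, SE 0.32), OLFML3 (2.08, SE 0.28), PADI2 (1.99, SE 0.23), PDPN (1.88, SE 0.33) and GCHFR (1.84, SE 0.26) also rose, each in 5 of 5 libraries.

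S100A12, a calgranulin of monocytes and neutrophils, fell from CD11c-low to CD11c-high cells by 4.36 on the log2 scale (SE 0.65, adjusted p = 0.00124), from 205 ± 173 to 8.83 ± 7.48 CPM (134 CPM in low cells without replicate 5), and S100A8 by 3.37 (SE 0.63, adjusted p = 0.00344). Within the 3′ libraries, that is without replicate 5, these values were −3.70 and −2.73. LYVE1 fell by 3.90 (SE 0.35, adjusted p = 0.000261), from 603 ± 185 to 49.2 ± 30.4 CPM, SELENOP by 3.27 (SE 0.30, adjusted p = 0.000267) and F13A1 by 2.94 (SE 0.15, adjusted p = 3.12e-05). FCN1, a monocyte lectin (−3.43, SE 0.47), LILRB5 (−3.43, SE 0.19), RIPOR2 (−2.91, SE 0.25), S100A9 (−2.89, SE 0.54) and the proteoglycan VCAN (−2.88, SE 0.34) also fell, each in 5 of 5 libraries. ITGAX itself, which checks the antibody and is no finding, was higher by 0.77 (SE 0.10, adjusted p = 0.000802).

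By the same edgeR test, 2987 genes were higher and 2810 lower of 13728 tested (n = 5 pairs). Of these, 4972 moved the same way in every library, 401 were higher and 538 lower by 2-fold or more, and the median log2 fold change of all genes was 0.01. The 4 libraries of 3′ end alone gave 3598 higher and 3282 lower genes. Without the block, 251 were higher and 293 lower. Without replicate 2 the numbers were 1853 and 1753. Among macrophages at 5% mitochondrial RNA or less they were 1481 and 1547, and 1415 and 1082 with the parts taken within each cluster.

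CD11c-high and CD11c-low are ranges as well, and 7337 of 36283 macrophages (20.2%) lay within 0.1 of a threshold. Median RNA depth was 10552 ± 5229 UMIs in high and 5123 ± 2182 in low cells, and median antibody counts for CD11c were 22 to 30 and 3 to 5 in the 3′ libraries and 144 and 21 in replicate 5. Median total antibody counts were 1477.5 ± 777 in high and 847 ± 600 in low cells, and were larger in the high class of each library. Lipid-associated macrophage-like cells made up 40.6% ± 13.5 of the high and 8.74% ± 3.26 of the low class, monocyte-like cells 3.81% ± 2.65 and 34.4% ± 15.6, LYVE1/FOLR2 macrophage-like cells 6.33% ± 1.21 and 42.1% ± 11.5, and cluster 1 30.6% ± 13.7 and 9.44% ± 7.96. Medians over cells were 25134 ± 6178 CPM of lipid-associated genes in high and 6074 ± 885 in low cells, 1079 ± 504 and 5550 ± 1275 CPM of resident macrophage genes, and 2224 ± 752 and 5291 ± 2546 CPM of monocyte genes. They were 344 ± 55.8 and 173 ± 110 CPM for dendritic cell genes and 22813 ± 10901 and 15161 ± 7808 CPM for MHC class II genes. Each is again a sum over a list's genes, so abundant members such as SPP1, APOE and APOC1 weigh most in the lipid-associated value.

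**Figure D3:**
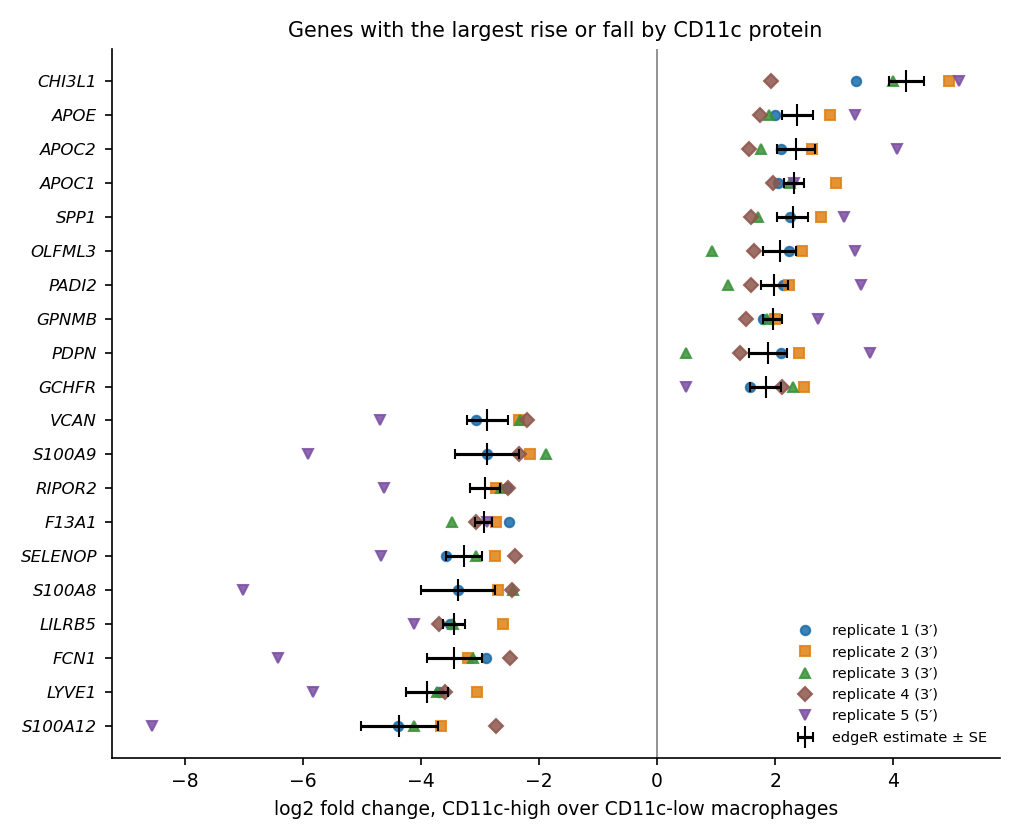
Log2 fold change of CD11c-high over CD11c-low macrophages (x axis) for the 10 largest rises and 10 largest falls (y axis). Symbols are the 5 libraries and the black bar is the edgeR estimate with SE, and the 5′ library lies farthest out for S100A12 at −8.56, where the other libraries lie between −4.38 and −2.74.

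Among the gene lists in the CD11c contrast (log2 fold change ± SE, n = 5), 14 of 15 resident macrophage genes fell and 1 rose, the same adjusted over the list alone, with CD209 at −3.05 ± 0.12 and FOLR2 at −2.73 ± 0.12. Its camera adjusted p was 2.87e-26, and it was the only list in either contrast to pass with an estimated correlation (adjusted p = 0.0263). Of 12 monocyte genes, 12 fell, also adjusted over the list alone, with CD300E at −2.24 ± 0.14 (adjusted p = 3.56e-11, and adjusted p = 0.266 with an estimated correlation). Of 16 lipid-associated genes, 11 rose and 5 did not pass, 11 also adjusted over the list alone, with CD9 at 1.77 ± 0.16 and TREM2 at 1.63 ± 0.16 (adjusted p = 3.58e-08, and adjusted p = 0.266 with an estimated correlation). Of 13 MHC class II genes, 9 rose and 4 did not pass, with 9 higher and 1 lower adjusted over the list alone. HLA-DQA1 (1.11 ± 0.21) and the peptide exchange subunit HLA-DMA (0.58 ± 0.12) rose, at adjusted p = 0.00965 for the list, or adjusted p = 0.612 with an estimated correlation.

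Of 19 lysosome genes, 8 rose and 11 did not pass, 8 also adjusted over the list alone, with the protease CTSD at 0.82 ± 0.13 and the cholesterol carrier NPC2 at 0.70 ± 0.11 (camera adjusted p = 0.0156, adjusted p = 0.734 with an estimated correlation and adjusted p = 0.0751 with fry). The lysosome list did not pass without replicate 3 (adjusted p = 0.0975). Of 12 proliferation genes, 11 rose and 1 did not pass, and 12 rose adjusted over the list alone, with TYMS at 1.19 ± 0.17 and RRM2 at 0.83 ± 0.11 (adjusted p = 5.48e-05, and adjusted p = 0.369 with an estimated correlation). Without cycling cell-like cells and cluster 7 the values were −1.21 for TYMS and −1.97 for RRM2, again the opposite direction, with cluster 10 kept. With cluster 10 left out too they were −0.013 and −0.54, and neither passed. Of 12 complement genes, 4 fell, 1 rose and 7 did not pass, the same adjusted over the list alone. Properdin, encoded by CFP (−3.05 ± 0.45), and CR1 (−2.76 ± 0.21) fell and C3 rose (1.56 ± 0.30), with list adjusted p = 0.00972, or adjusted p = 0.369 with an estimated correlation. Of 14 scavenger receptor genes, 7 fell, 1 rose and 6 did not pass, with 8 and 3 adjusted over the list alone. STAB1 (−2.04 ± 0.20) fell and OLR1, the receptor of oxidised LDL, rose (1.55 ± 0.19), at list adjusted p = 0.00471, or adjusted p = 0.369 with an estimated correlation.

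Of 10 iron and haem genes, 5 fell and 5 did not pass, with 5 lower and 1 higher adjusted over the list alone, among them SLC40A1 at −2.27 ± 0.11 (camera adjusted p = 0.0103, and adjusted p = 0.266 with an estimated correlation). Of 15 inflammatory genes, 9 fell, 1 rose and 5 did not pass, the same adjusted over the list alone, with CXCL8 at −1.22 ± 0.22 and PTGS2 at −1.12 ± 0.08. This list had adjusted p = 0.0226, or adjusted p = 0.369 with an estimated correlation, and did not pass without replicate 1 (adjusted p = 0.0631) or 3 (adjusted p = 0.0717). Of 16 dissociation stress genes, 7 fell and 9 did not pass, 7 also adjusted over the list alone, with EGR1 at −0.86 ± 0.11 and HSPA1B at −0.72 ± 0.13 (adjusted p = 0.0134, and adjusted p = 0.612 with an estimated correlation). It moved with the resident, monocyte, complement, scavenger receptor, iron and haem, and inflammatory lists.

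The remaining lists did not pass camera. Of 16 cholesterol and lipid handling genes, 4 rose and 7 fell, with 4 and 8 adjusted over the list alone. ABCA1 (−0.88 ± 0.12) fell and the apolipoprotein gene APOE rose (list adjusted p = 0.445). Of 11 dendritic cell genes, 3 rose and 2 fell, with 4 and 3 adjusted over the list alone (CADM1 1.79 ± 0.13, CLEC10A −1.51 ± 0.20, list adjusted p = 0.552). Of 14 interferon genes, 3 rose and 1 fell, the same adjusted over the list alone (IFI6 0.61 ± 0.08, ISG15 0.60 ± 0.14, list adjusted p = 0.623). Of 14 checkpoint and costimulation genes, 4 rose and 4 fell, the same adjusted over the list alone (HAVCR2 0.57 ± 0.09, LILRB2 −1.40 ± 0.14, list adjusted p = 0.901). Of 15 growth factor and matrix genes, 2 rose and 5 fell, with 4 and 6 adjusted over the list alone (PLAUR 0.61 ± 0.09, IGF1 −2.11 ± 0.31, list adjusted p = 0.552). Of 13 hypoxia and glycolysis genes, 3 rose and 5 fell, with 5 and 5 adjusted over the list alone (LDHA 0.49 ± 0.10, SLC2A3 −0.89 ± 0.11, list adjusted p = 0.552).

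Markers of other cell types did not pass as lists in the CD11c contrast. Of 14 acinar genes, 1 fell, CPB1 (−0.72 ± 0.24), and 0 passed adjusted over the list alone, while 4 were lower at an unadjusted p under 0.05 in edgeR and 4 past the threshold in DESeq2. The list's adjusted p was 0.164, but it passed without replicate 1 (adjusted p = 0.0249) and without replicate 4 (adjusted p = 0.0369), and CPB1 did not pass without replicate 2 (−0.77) or 3 (−0.53). Of 12 T and NK cell genes, 2 rose and 3 fell, with 2 and 5 adjusted over the list alone (IL7R 1.14 ± 0.21, CD3G −1.46 ± 0.32, list adjusted p = 0.552). Of 4 B and plasma cell genes, DERL3 rose (1.07 ± 0.17, list adjusted p = 0.927), and of 5 stromal and endothelial genes, 1 rose and 2 fell (DCN −2.02 ± 0.34, at 1.01 ± 0.374 CPM in low cells, list adjusted p = 0.552, and adjusted p = 0.0405 with fry), both the same adjusted over the list alone. Of 5 neutrophil genes, 2 rose and 1 fell, with 2 and 2 adjusted over the list alone (G0S2 1.40 ± 0.29, FFAR2 −1.46 ± 0.20, list adjusted p = 0.927). Of 3 mast cell genes, HPGDS rose (0.65 ± 0.23, list adjusted p = 0.552) but did not pass adjusted over the list alone, nor without replicate 1 (0.50), 2 (0.72), 4 (0.63) or 5 (0.49). Median and mean differed in sign for the dendritic (−0.10 and 0.10), checkpoint (0.19 and −0.06), hypoxia (0.17 and −0.09) and neutrophil (−0.01 and 0.07) lists. Both were negative for the interferon list (−0.10 and −0.03) and the B and plasma cell list (−0.47 and −0.09), which camera placed higher.

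The fourth question was which surface proteins set RNA-defined macrophage subsets apart, tested by edgeR on 129 antibodies in each subset against all other macrophages (n = 5 libraries, log2 fold change ± SE). Folds and values per 10000 give an antibody's share of antibody counts after TMM scaling. More or less antibody is meant in that sense here and below, not per cell. Shares without TMM scaling were compared only in the alternative with library size only. LYVE1/FOLR2 macrophage-like cells bound more antibody against HLA-DR, the antigen-presenting MHC class II molecule (1.34 ± 0.08, adjusted p = 9.73e-05), at 835 ± 305 against 327 ± 112 per 10000 antibody counts. They also bound more antibody against CD163 (1.04 ± 0.12, adjusted p = 0.00178), the Fc receptor CD32 (0.85 ± 0.12), CD28 (0.82 ± 0.19), the costimulatory ligand CD86 (0.80 ± 0.04) and CD47 (0.68 ± 0.08). They bound less of those against the fatty acid receptor CD36 (−1.38 ± 0.20), the transferrin receptor CD71 (−1.26 ± 0.29), CD48 (−1.16 ± 0.16), the integrin CD11a (−1.15 ± 0.11), the aminopeptidase CD13 (−0.95 ± 0.11) and CD11c (−0.93 ± 0.05). In all, 30 antibodies were higher and 25 lower, while the 6 isotype controls lay between −0.16 and 0.10. With library size only in place of TMM, 15 were higher and 34 lower. The higher number was 19, 10, 10 and 19 without replicates 1, 2, 3 and 5, and CD28 did not pass without replicate 2 (0.78) or 3 (0.75), nor CD71 without replicate 3 (−1.03).

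Lipid-associated macrophage-like cells bound more antibody against CD71 (1.31 ± 0.27, adjusted p = 0.0130), at 247 ± 174 against 84.9 ± 27.6 per 10000, and against the lysosomal membrane protein CD107a (1.09 ± 0.21, adjusted p = 0.0105). CD36 (0.80 ± 0.19, higher in 4 of 5 libraries), CD13 (0.57 ± 0.05), the oxidised LDL receptor LOX-1 (0.49 ± 0.07) and CD11c (0.49 ± 0.05, adjusted p = 0.00131) were also higher. CD35, the complement receptor encoded by CR1 (−0.65 ± 0.11), CD14 (−0.62 ± 0.13), CD11b (−0.47 ± 0.06), CD7 (−0.44 ± 0.07), CD38 (−0.43 ± 0.08) and the ectonucleotidase CD39 (−0.41 ± 0.10) were lower. CD7 stood at only 2.20 ± 1.23 against 2.97 ± 1.49 per 10000. In all, 12 antibodies were higher and 47 lower, with isotype controls between −0.10 and 0.08. Median antibody counts per cell were 1168 and 1114.5 in clusters 2 and 4 of this class. They were 728, 860, 612 and 435 in clusters 0, 1, 3 and 6, and 885 to 1096 in clusters 7 to 10. A lower share in this class therefore need not mean less antibody per cell. The lower number was 26, 20, 13, 15 and 17 without replicates 1 to 5, and 20 and 30 with own clusters at resolutions 0.5 and 1.5, and limma on log-ratio means called 19 higher. CD38 and CD39 did not pass without replicate 3 (−0.36 and −0.29), 4 (−0.38 and −0.39) or 5 (−0.35 and −0.37), CD36 without 3 (0.74) or 5 (0.88), CD14 without 3 (−0.53) and CD71 without 4 (1.42).

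Monocyte-like cells bound more antibody against CD35 (2.40 ± 0.51, adjusted p = 0.0158), at 58.8 ± 41.3 against 9.56 ± 3.33 per 10000, and against CD36 (1.90 ± 0.46, adjusted p = 0.0198). CD48 (1.57 ± 0.08, adjusted p = 0.000231), CD52 (1.49 ± 0.22), the NAD-consuming ectoenzyme CD38 (1.38 ± 0.08) and CD13 (1.33 ± 0.24) were higher as well. HLA-DR (−1.56 ± 0.21, adjusted p = 0.00529), CD39 (−1.16 ± 0.20), the integrins CD49f (−0.86 ± 0.15), CD49d (−0.83 ± 0.08) and CD11c (−0.81 ± 0.18) and the tetraspanin CD81 (−0.73 ± 0.19) were lower. In all, 27 antibodies were higher and 27 lower. The isotype controls lay between −0.32 and 0.04, and 1 of 6 was also lower past the test. Without replicate 1 the numbers were 12 and 8, and the lower number was 16 without replicate 2. CD35 (2.09) and CD36 (1.64) did not pass without replicate 1, nor did CD11c and CD81 without replicate 1 (−0.85 and −0.67) or 2 (−0.71 and −0.68).

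Cycling cell-like macrophages bound more antibody against the integrins CD49d (0.51 ± 0.11), CD49f (0.49 ± 0.10) and CD29 (0.35 ± 0.06) and the Fc receptor CD64 (0.26 ± 0.06), and less against CD36 (−1.35 ± 0.17), CD35 (−0.91 ± 0.19) and CD38 (−0.43 ± 0.07). These were the 4 higher and 3 lower antibodies, with edgeR adjusted p from 0.0133 to 0.0468 and isotype controls between −0.10 and 0.01. Without called doublets, an alternative added after seeing the data, 1 was higher and 2 lower, and limma on log-ratio means called 8 and 5. With library size only 7 were lower, and with own clusters at resolution 1.5, 9 were higher. No antibody passed for this subset without replicate 1, 2 or 3, where the edgeR counts were 0 and 0 (CD36 −1.28, −1.28 and −1.17), and replicate 4 held 50 of these cells with at least 100 antibody counts. At an unadjusted p under 0.05 they were 14 and 10, 9 and 11, and 15 and 12, and limma called 1 lower antibody in each of these fits. CD49d, CD49f and CD64 did not pass without replicate 5 (0.56, 0.47 and 0.27) and CD35 without replicate 4 (−0.84).

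The unnamed clusters were tested by number, a choice made after seeing the data. Cluster 1 bound less antibody against CD36 (−2.84 ± 0.16, adjusted p = 6.47e-08), at 8.56 ± 4.78 against 57.3 ± 19.9 per 10000, and against CD35 (−1.15 ± 0.18), CD13 (−1.06 ± 0.10), CD71 (−0.91 ± 0.22), CD163 (−0.83 ± 0.09, adjusted p = 3.75e-05) and CD86 (−0.82 ± 0.10). It bound more against CD45RO (0.51 ± 0.08), CD49d (0.46 ± 0.08), CD49f (0.41 ± 0.08), CD11c (0.39 ± 0.10), the adhesion molecule CD58 (0.38 ± 0.08) and CD39 (0.38 ± 0.10). In all, 12 antibodies were higher and 19 lower, with isotype controls between 0.10 and 0.20, and the rises named lay between 0.38 and 0.51. The higher number was 6, 2, 6 and 5 without replicates 1, 2, 3 and 5, and the lower number 9 without replicate 2. Without replicate 2, CD36, CD13, CD163 and CD86 passed, and the other 8 antibodies named did not (CD35 −1.24, CD71 −0.84, CD45RO 0.49, CD49d 0.41, CD49f 0.34, CD11c 0.33, CD58 0.35 and CD39 0.28). CD39 did not pass without replicate 1 (0.38), 3 (0.29) or 5 (0.23) either, nor CD11c without 1 (0.35) or 5 (0.25), nor CD49f without 5 (0.29).

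Cluster 7 also bound less antibody against CD36 (−1.12 ± 0.14), CD35 (−0.89 ± 0.13), CD163 (−0.62 ± 0.06, adjusted p = 0.000817), CD38 (−0.58 ± 0.06), CD13 (−0.55 ± 0.11) and CD86 (−0.40 ± 0.08). It bound more against CD11c (0.48 ± 0.06), CD49f (0.47 ± 0.08), CD49d (0.47 ± 0.07), CD58 (0.32 ± 0.04), CD39 (0.32 ± 0.07) and CD29 (0.31 ± 0.05). In all, 11 antibodies were higher and 13 lower by edgeR, with isotype controls between −0.09 and 0.12, and 17 and 33 by limma on log-ratio means. The higher number was 6 without replicate 3 and 20 without replicate 5. CD39 did not pass without replicate 1 (0.33), 2 (0.31) or 3 (0.32), CD49f without 2 (0.45) or 3 (0.46) and CD86 without 3 (−0.40). With no library block, the numbers of higher and lower antibodies were 2 and 6 for LYVE1/FOLR2, 0 and 0 for lipid-associated, 4 and 0 for monocyte-like and 0 and 0 for cycling cell-like macrophages, 0 and 3 for cluster 1 and 0 and 0 for cluster 7. At an unadjusted p under 0.05, edgeR without the block gave 7 and 13, 6 and 1, 14 and 9, 3 and 3, 0 and 8, and 2 and 5 in the same order.

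**Figure D4:**
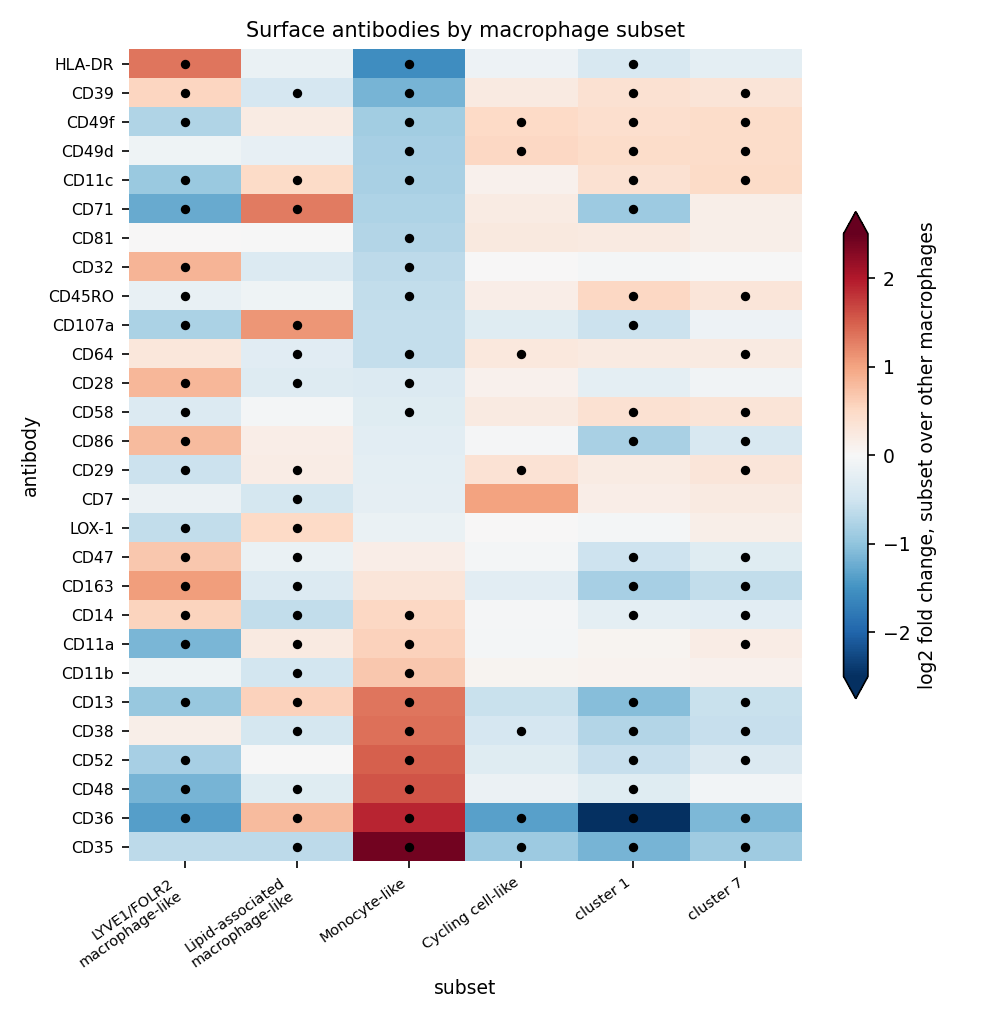
Log2 fold change of antibody counts in a subset over the other macrophages (colour) for 28 antibodies (y axis) in 6 subsets (x axis); a dot marks an edgeR adjusted p under 0.05. CD36 is lowest in cluster 1 (−2.84) and CD35 highest in monocyte-like cells (2.40).

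The last question was how far a surface protein and its messenger RNA went together across single macrophages. Spearman's rho was computed within each library, across cells, which are not independent replicates, so no p-value is given. Over the 72 pairs kept, the median of the mean rho was 0.0713, with 13 pairs above 0.2, 27 above 0.1 and 8 below 0. In 52 pairs rho was positive in every library. HLA-DRA and HLA-DR had the highest value among the pairs measured in all libraries (0.508 ± 0.0975, SD, n = 5), followed by CD163 (0.434 ± 0.0965), CD36 (0.394 ± 0.0774), ANPEP with CD13 (0.373 ± 0.0806), CD52 (0.344 ± 0.0900) and OLR1 with LOX-1 (0.316 ± 0.0684). ITGA6 with CD49f (0.277 ± 0.118), CD48 (0.237 ± 0.0699), ITGAX with CD11c (0.236 ± 0.114) and CD81 (0.230 ± 0.124) were lower. CD47 (−0.0123 ± 0.0895), CD79B (−0.0163 ± 0.0189) and CD7 (−0.0537 ± 0.0571) had the lowest values, and their signs were not stable: CD7 was 0.0267 with antibody counts per 10000, and CD47 was 0.00192 and CD79B 0.0031 in thinned cells. The negative mean of CD47 rested on replicate 5 (−0.160), while the other libraries lay between −0.0174 and 0.0708. RNA depth limits these values, and in cells thinned to 2000 UMIs the median was 0.0384. Antibody signal played no part in which pairs were kept, so antibodies with few counts enter the median. CD7 antibody, for one, stood at 2.97 per 10000 in macrophages outside the lipid-associated class. A low rho can therefore also come from few antibody counts.

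**Figure D5:**
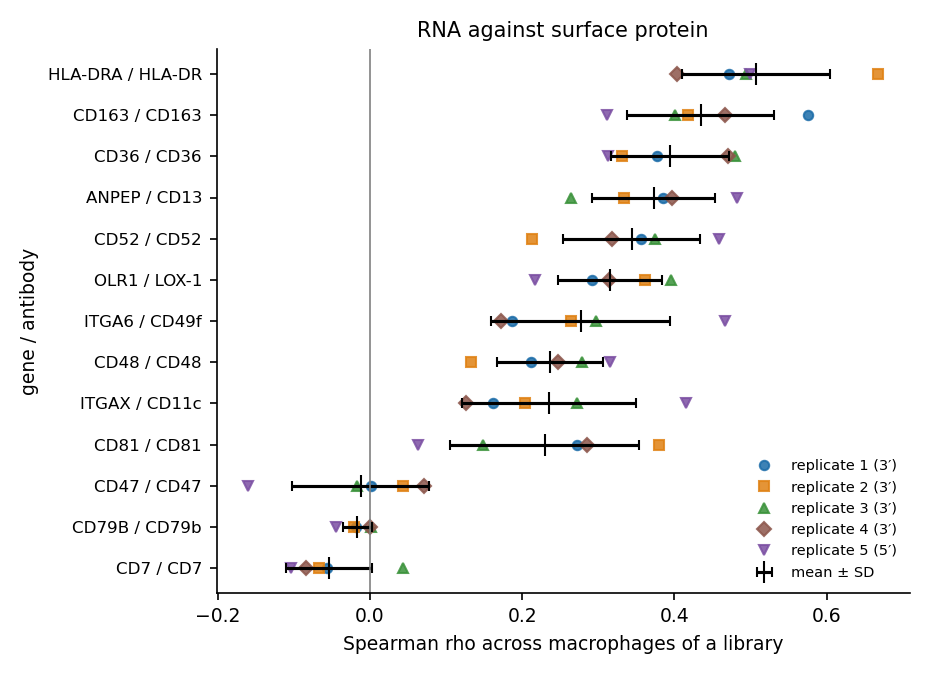
Spearman's rho between RNA and antibody signal across the macrophages of a library (x axis) for 13 gene and antibody pairs (y axis). Symbols are the 5 libraries and the bar is the mean with SD, from 0.508 for HLA-DRA and HLA-DR to −0.0537 for CD7.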

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

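The tests of cluster mix and RNA depth behind both RNA contrasts were chosen after the result was seen. Splits for clusters 1 and 7 and for the 3′ panel concern comparisons that were themselves added after seeing the data, and the other tests here were set before. Of 139 groups of 5 libraries tested for a library far from the others, 9 held one, where chance gives about 1 in 20. Of these, 6 were genes of the CD11c contrast in which replicate 5, the only 5′ library, fell further than the others: log2 folds of −8.56 for S100A12 (others −4.38 to −2.74), −5.83 for LYVE1 (−3.72 to −3.05), −6.42 for FCN1 (−3.20 to −2.49), −7.01 for S100A8 (−3.37 to −2.45), −4.62 for RIPOR2 (−2.73 to −2.53) and −5.91 for S100A9 (−2.88 to −1.88). The 5′ library differs from the rest in donor, library end and antibody panel at once, and these were not told apart. In cycling cell-like cells, CD29 antibody stood at 0.16 in replicate 5 (others 0.37 to 0.43). In replicate 1, CD48 antibody stood at 1.88 in monocyte-like cells (others 1.43 to 1.54) and CD163 antibody at −0.91 in cluster 7 (others −0.59 to −0.53). Data outside the comparisons also held a signal: barcodes with at least 1000 UMIs that the authors left out carried a mean of 8509 CPM of acinar RNA (211 to 22834 over libraries, and 4928 without replicate 2) and 1707 CPM of T and NK cell RNA (359 to 3504), against 159 and 86.1 CPM in the deposited cells and 1210 and 573 CPM in barcodes of 10 to 100 UMIs. In replicate 5 the acinar value was lower in the left-out barcodes (211 CPM) than in those of 10 to 100 UMIs (451 CPM).

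The cycling cell-like share ranged from 0.995% to 11.3% between libraries. A difference in RNA depth would bring the libraries together once every macrophage is thinned to 2000 UMIs, yet the share of macrophages with at least 2 UMIs of 6 cycling genes still differed 97.3-fold between the highest and lowest library (14.2% and 0.146%, the latter 7 of 4795 cells), against 16.7-fold before thinning. Without called doublets the cycling cell-like share differed 12.4-fold, but this cannot decide on doublets. The number called per library was set by an assumed rate, at 878 in replicate 1, which held 1183 cycling cell-like cells. Had all 878 been cycling cell-like, the share in replicate 1 would still have stayed well above that in replicate 4. The size of these fold differences rests on replicate 4, without which they were 3.31-, 2.63- and 3.16-fold. Donor, tissue handling and cell isolation cannot be separated with 1 library per donor, and no biological explanation was tested, because the labels give the donors no groups.

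In 1924 of 36364 macrophages acinar RNA lay above a Poisson limit, a mean of 5.45% ± 2.59 over libraries (SD, n = 5). The limit grew with a cell's UMIs, and free RNA in that proportion would pass it in about 1% of cells. This argues against free RNA in proportion to UMIs as the whole source. An equal amount of free RNA per droplet would pass the limit more often in cells with few UMIs, and was not tested. Doublets with acinar cells would carry more RNA. The median UMIs of the macrophages above the limit were 1.05 ± 0.163 times those of other macrophages, under the 1.3 set for doublets. Of these cells 8.16% ± 4.89 were called doublets, against 6.74% of all macrophages. The calls were made by adding pairs of deposited cells, selected as macrophages. They therefore cannot speak for or against doublets with acinar cells. Uneven free RNA, an equal amount of it per droplet, debris on the cell surface and uptake of acinar cells stay open. No biological explanation was tested.

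For both RNA contrasts, the classes differed in cluster mix and in depth. With classes taken within each cluster, called genes kept a median of 0.337 ± 0.118 of their log2 fold change for CD163 and 0.272 ± 0.0529 for CD11c (SD over libraries), which decides nothing alone, since classes within clusters also differ less in protein. Still called the same way were 2081 of 5915 genes for CD163 and 2148 of 5797 for CD11c. A mix of the authors' clusters was therefore not the whole cause of either. Classes could still differ in the mix of finer states within a cluster, which was not tested. With every cell thinned to 2000 UMIs, the share kept was 0.961 ± 0.0754 and 1.01 ± 0.0565. Of the called genes, 3847 of 5915 for CD163 and 4119 of 5797 for CD11c were still called the same way. The typical fold thus did not rest on the greater weight of deep cells in the sums. Thinning leaves each cell's expected gene proportions unchanged, so it cannot decide whether the folds come with the difference in RNA depth between the classes. How much of each fold comes from cluster mix or depth stays open, and no biological explanation was tested.

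For each count of calls below, 1 to 3 of 100 splits of the 10 sums, the real one included, gave as many. The real value and the highest of the other splits were 5915 and 83 genes for CD163, with 1 split as large, and 5797 and 0 for CD11c (1). They were 55 and 5 antibodies for LYVE1/FOLR2 (1), 59 and 37 for lipid-associated (1), 54 and 10 for monocyte-like (1) and 7 and 9 for cycling cell-like macrophages (3), 31 and 42 for cluster 1 (3) and 24 and 1 for cluster 7 (1). In the 4 libraries of 3′ end, with 32 splits and 1 as large each time, they were 65 and 0 for LYVE1/FOLR2, 37 and 6 for lipid-associated, 62 and 2 for monocyte-like cells and 25 and 1 for cluster 1. In cycling cells and cluster 1 another split called more than the real one. The high and low sums of a library are paired, and most of these splits part fewer pairs than the real one. Among the splits that part every pair (14 of 100 and 8 of 32, the real one included) the highest other count was 0 in each, but they are too few for a share under 0.05. Whether chance can be excluded therefore rests on splits that do not keep the pairing.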

How the results depend on the processing

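Alternatives marked added were chosen after seeing the data. No alternative turned the direction of a named gene except those given here, and the cause was not tested for any change unless stated. Of 1973 comparisons of named CD11c genes with an alternative, 1819 kept direction and side of the threshold, 144 no longer passed and 10 reversed. For CD163 these were 1737, 133 and 7 of 1877, and for named antibodies 536 of 665 held and 129 no longer passed. For lists 291 of 320 held, 25 no longer passed and 4 newly passed. Of 288 counts, shares and medians 214 held and 74 moved, and of 91 RNA and protein pairs 82 held.

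With no replicate block, which ignores the pairing of classes by donor, calls fell to 132 higher and 65 lower genes for CD163 and 251 and 293 for CD11c. Antibodies fell to 2 and 6 for LYVE1/FOLR2, 0 and 0 for lipid-associated, 4 and 0 for monocyte-like, 0 and 0 for cycling cell-like macrophages, 0 and 3 for cluster 1 and 0 and 0 for cluster 7 by edgeR (at an unadjusted p under 0.05, 7 and 13, 6 and 1, 14 and 9, 3 and 3, 0 and 8, and 2 and 5). It ended the calls of 63 named CD11c genes, 68 named CD163 genes and 54 antibodies, and turned no direction. At 5% mitochondrial RNA or less, 1606 and 1846 genes passed for CD163 and 1481 and 1547 for CD11c, among 8026 macrophages, fewer cells. With parts taken within each cluster (added), they were 1057 and 1103, and 1415 and 1082.

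With an estimated correlation, 0 lists passed camera for CD163 and 1 for CD11c (5 and 4 at an unadjusted p under 0.05), where 10 and 11 passed with the preset one. With fry, a test against no change and not against other genes, 10 and 11 passed, but proliferation for CD163 (adjusted p = 0.0575) and lysosome for CD11c (0.0751) did not, while checkpoint for CD163 (0.0245) and stromal for CD11c (0.0405) did. By limma on log-ratio means, 8 and 5 antibodies passed for cycling cells and 17 and 33 for cluster 7, and 19 were higher for lipid-associated cells. With library size only, 7 were lower for cycling and 15 higher for LYVE1/FOLR2 cells. With own clusters, 20 (resolution 0.5) and 30 (1.5) were lower for lipid-associated cells and 9 higher for cycling cells (1.5), and without called doublets (added) 1 was higher for cycling cells. Shares moved with the clustering: at 0.5 and 1.5, 0% and 0.227% for interferon, 10.5% and 14.0% for lipid-associated and 20.9% and 5.26% for cDC2-like cells, and 6.97% at 0.5 for monocyte-like cells. The cycling cell-like name then also took a cluster led by DNA replication genes, of 1973 cells at 0.5 and 1410 at 1.5. The cluster named cDC2-like at 0.5 shared 5 of its 10 leading genes (EREG, THBS1, ANPEP, TFPI, CCR2) with the authors' monocyte-like cluster 3, so 20.9% and 6.97% reflect the naming as well. At 5% mitochondrial RNA or less the LYVE1/FOLR2 share was 12.5%. The median rho was 0.0384 in thinned cells.

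Leaving out each library in turn gave 2048 to 3098 higher and 1877 to 3452 lower genes for CD163, 1853 to 3598 and 1753 to 3282 for CD11c, and 10 to 10 and 9 to 12 lists. Antibodies ranged from 0 to 5 higher and 0 to 3 lower for cycling, 10 to 21 higher for LYVE1/FOLR2, 13 to 26 lower for lipid-associated, 12 to 30 higher and 8 to 31 lower for monocyte-like cells, 2 to 11 and 9 to 21 for cluster 1 and 6 to 20 higher for cluster 7.

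Proliferation genes reversed without cycling cell-like cells and cluster 7 (added), with cluster 10, also led by replication genes, kept: BIRC5 0.59, TYMS 1.53, CENPF 0.38 and CDK1 0.89 for CD163, and RRM2 −1.97, TYMS −1.21, CDK1 −0.92 and PCNA −0.15 for CD11c. Without cluster 10 as well (added), BIRC5 was 0.10 and CENPF 0.11 for CD163, and RRM2 −0.54, TYMS −0.013 and CDK1 −0.13 for CD11c, none past the threshold. Within clusters (added), FCER1A was 0.028 for CD163, and MX2 0.068, VSIR 0.035 and PECAM1 0.075 for CD11c. RLE factors changed no named gene's call or direction. Alternatives of the CD206 and tissue contrasts were not run, because those contrasts were not. Simulated counts had the depth and number of these libraries and an assumed spread, which were not separated. In these, edgeR found 44% and 41% of changes of log2 0.5, so a gene without a call cannot be read as unchanged.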

Other observations

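Antibodies found only in the 3′ panel added further surface proteins to the subsets, tested by edgeR over 140 antibodies in 4 libraries, a choice made after seeing the data (log2 fold change ± SE, n = 4). Lipid-associated macrophage-like cells bound more antibody against CD72 (0.84 ± 0.05, adjusted p = 0.00182), the SIRP alpha receptor CD172a (0.61 ± 0.07, adjusted p = 0.00617) and the tetraspanins CD63 (0.94 ± 0.22) and CD9 (0.75 ± 0.17), and less against CD93 (−0.30 ± 0.04) and the selectin ligand CD162 (−0.29 ± 0.08). LYVE1/FOLR2 macrophage-like cells bound less against CD172a (−1.09 ± 0.11, adjusted p = 0.00267), podoplanin (−0.91 ± 0.20) and CD9 (−0.86 ± 0.13). Monocyte-like cells bound more against the chemokine receptor CD192, encoded by CCR2 (1.33 ± 0.19, adjusted p = 0.00853), CD93 (1.17 ± 0.12) and CD162 (0.81 ± 0.15), and less against CD9 (−1.46 ± 0.43), CD72 (−1.32 ± 0.16), podoplanin (−1.10 ± 0.24) and CD172a (−0.71 ± 0.21). Cluster 1 bound more antibody against podoplanin (0.80 ± 0.13, adjusted p = 0.0261) and less against CD192 (−0.40 ± 0.07), each in 4 of 4 libraries. Among pairs measured in these libraries alone, rho across cells was 0.524 ± 0.0722 for CD9 and 0.402 ± 0.0804 for podoplanin and PDPN (SD, n = 4).

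Macrophages with acinar RNA above background were found in each class measured, at 10.1% ± 11 of LYVE1/FOLR2 macrophage-like (5.22% without replicate 3, which held 29.5%), 9.89% ± 4.29 of cycling cell-like, 4.42% ± 1.57 of unnamed, 4.10% ± 1.5 of lipid-associated and 3.53% ± 1.69 of monocyte-like cells (SD, n = 5 libraries, not tested between classes). In these cells PRSS1, the trypsinogen gene, stood at 180 CPM and CLPS, the colipase gene, at 169 CPM, against 12.8 and 13.8 CPM in the other macrophages. Both genes are among the markers that selected these cells, so a difference was set by the selection. In barcodes of 10 to 100 UMIs PRSS1 and CLPS stood at 149 and 123 CPM. Own clusters at resolution 1.5 included an acinar cell-like cluster of 1289 cells. Among all deposited cells, cDC2-like cells included, RNA of other cells above background was found in 3.43% to 9.18% per library for acinar, 1.68% to 3.55% for T and NK cells, 0.513% to 1.56% for B and plasma cells and 0.151% to 0.342% for endocrine cells.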
